A study of Mus musculus with 70 samples.

How the data were processed

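The deposited values were measured on single-colour Affymetrix arrays of mouse RNA, per the labels after 2 rounds of T7 amplification from laser-captured material. Neurons were EYFP-labelled layer V cells, 700 to 800 per sample from sections of 8 micrometres, and white matter was cut from the corpus callosum in sections of 20 micrometres, from 10 slides per sample. The authors normalized the arrays with RMA, and the labels name RMA, affy and limma without versions or the order of steps. The deposited values are log2 expression, rounded to 1 decimal. The medians of the arrays differ between the tissues and hardly within them, so the tissues look normalized separately. The table holds 22690 probe sets. Of these, 64 control probe sets, 691 assigned to several genes and 1555 assigned to none were left out of the gene-level tests. The 20380 probe sets with exactly 1 gene gave 12393 genes, each represented by the probe set with the highest mean over all arrays of both tissues. No probe set is assigned to Plp1, and 3 are assigned to Cnp. No pair of arrays was identical.

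Groups were taken from the labels of genotype, age and tissue. Each tissue was fitted with limma 3.58.1 in R 4.3.3, with 12 group means and empirical Bayes moderation of the spread, which is shared by all groups of the tissue. Contrasts were each mutant against WT averaged with equal weight over the 4 ages, each mutant against WT at each age, CNP-KO against PLP-KO averaged over ages, 12 against 1 month in WT, and the difference of each mutant's effect between 12 and 1 month. White matter was compared with neurons over the WT arrays whose age and replicate number occurred in both tissues, with age and replicate number as the block. The same number need not be the same animal: WT 1-month replicate 2 had Xist at 9.3 in neurons and 4.9 in white matter. Tests were two-sided and adjusted by Benjamini-Hochberg over all genes within a contrast, with a threshold of 0.05. Replicate numbers were not used to pair arrays within a tissue: residuals of arrays with the same number had a median correlation of 0.03 in neurons and 0.05 in white matter, and of 0 across the tissues, so the block of the tissue comparison changes little and its result without the block was computed too.

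The 23 gene lists were fixed before the data were examined, as were the design, the rule for named genes and the first set of alternatives below. Lists were tested with camera, with the preset correlation of 0.01, and adjusted over the lists within a contrast. Each was also tested with camera and an estimated correlation, and with fry. They cover myelin and mature oligodendrocytes, oligodendrocyte precursors, cholesterol synthesis, homeostatic and activated microglia, complement and Fc receptors, antigen presentation, interferon response, reactive astrocytes, astrocyte identity, T cells, endothelial and mural cells, layer V neurons, interneurons, synapse, axonal cytoskeleton and transport, axonal injury, unfolded protein and integrated stress response, immediate early genes, oxidative phosphorylation, glycolysis with lactate or glucose transport, cell cycle and ribosomal proteins. They hold 435 measured genes, 2 of them in more than 1 list. The target genes Plp1 and Cnp are in no list.

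Genes were named by a fixed rule. For the averaged, the WT age and the tissue comparisons, these were the 8 highest and 8 lowest log2 differences past the threshold, for the averages with the same sign at all 4 ages. For the single-age, direct and 12 against 1 month comparisons, the 3 highest and 3 lowest were named, or, where none passed, the 3 with the smallest p. Up to 4 members of a list with the smallest p in an averaged comparison, and Cnp, were named as well. Levels of Xist and Eif2s3y were chosen for naming after their values were seen, as were further levels of named genes at single ages. Names and the neighbours of Cnp came from the table of probe genes and from RefSeq genes of the assembly GRCm38.p6, of which no coordinate is printed. Of the 20380 probe sets, 20351 were matched by their gene identifier.

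The fits were tested on simulated data made from the residual spread. For CNP-KO against WT averaged over ages, 86.6% of genes changed by 0.5 on the log2 scale were recovered in neurons and 85.1% in white matter, and 100% of those changed by 1, among 12393 genes in each fit. For PLP-KO against WT averaged over ages in neurons, 91% and 100% were recovered. At a single age, in CNP-KO neurons at 6 months, 31.3% of changes of 0.5 and 86.6% of changes of 1 were recovered. False calls made up 7.3%, 4.5%, 6.3% and 6.5% of the calls in these simulations, counted outside the oxidative phosphorylation list, which was shifted as a whole by 0.5. The simulated noise was independent between genes and equal between arrays, whereas weights of the neuron arrays ran from 0.27 to 11. These shares may therefore not carry over to the real arrays.

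The alternatives set in advance were leaving out the 40% of genes with the lowest mean, quantile normalization within a tissue, a moderated spread with trend and robust estimation, array weights, the replicate number as a block, a fit of the compared groups only, all probe sets in place of 1 per gene, and leaving out each array in turn. Alternatives chosen after seeing the data were averages without the 1-month arrays, neuron fits without the 3 arrays whose weight was under 0.4 (WT 3-month replicate 3, WT 6-month replicate 2 and CNP-KO 12-month replicate 2), and joint quantile normalization of both tissues. Splits of the arrays into other groups of the same size were counted, 100 drawn at random where there were more.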

Results

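Gene expression was measured on 70 Affymetrix arrays in layer V neurons of the cortex and in corpus callosum white matter of mice, both taken by laser capture microdissection. The genotypes were wild type (WT), mice without proteolipid protein (PLP-KO, Plp1-/Y) and mice without cyclic nucleotide phosphodiesterase (CNP-KO, Cnp1-/-), both proteins of the oligodendrocyte and its myelin. Mice were 1, 3, 6 or 12 months old and labelled male. The sex-linked transcripts of a WT neuron array at 1 month go against that label, as given under the other observations. The neuron arrays numbered 36, with 3 in each of the 12 groups of genotype and age. The white matter arrays numbered 34, with 3 per group except 2 in WT at 1 month and 2 in WT at 3 months. Values were on the log2 scale. The median of an array lay between 5.1 and 5.2 in neurons and between 5.6 and 5.7 in white matter. The number of arrays limits the precision: the median standard error of a log2 difference averaged over ages was 0.09 in neurons and 0.08 in white matter, and at a single age 0.18 in neurons. Errors below are standard errors of the limma model, and p-values are adjusted over 12393 genes, unless stated. Group levels are means ± SD.

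The label CNP-KO could be checked by the level of its target. In white matter Cnp was 14.78 ± 0.23 (SD, n = 10) in WT, 14.85 ± 0.23 (SD, n = 12) in PLP-KO and 7.41 ± 0.64 (SD, n = 12) in CNP-KO. In neuron arrays it was 11.11 ± 0.34 in WT, 11.61 ± 0.35 in PLP-KO and 5.57 ± 0.58 in CNP-KO (SD, n = 12 each). The highest CNP-KO array was at 6.8 in neurons and 8.5 in white matter, and the lowest WT array at 10.6 and 14.4. All 3 Cnp probe sets were lower in CNP-KO white matter, with differences of -7.49, -7.4 and -3.29. In neurons, 2 of the 3 were (-1.3 and -5.54) and the other differed by -0.26 ± 0.08 (adjusted p = 0.2). No probe set is assigned to Plp1 in the table of probe genes, so the label PLP-KO was not checked in this way.

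White matter against neurons in WT asked which transcripts set the captured tissues apart. Myelin genes were far higher in white matter: Mobp by 6.98 ± 0.13, Mog by 6.85 ± 0.19 and Cnp by 3.64 ± 0.14 on the log2 scale (adjusted p = 7e-13, 9.7e-12 and 1e-10). Anln was higher by 7.34 ± 0.2, Stxbp3 by 7.03 ± 0.22, Ppp1r14a by 6.94 ± 0.15, the lysophosphatidic acid receptor Lpar1 by 6.79 ± 0.14, vimentin (Vim) by 6.7 ± 0.3 and Efhd1 by 6.56 ± 0.17. The neurofilament genes Nefm, Nefh and Nefl differed by -6.08 ± 0.35, -5.54 ± 0.21 and -5.15 ± 0.37, and the related Ina by -5.67 ± 0.31. Mal2 (-5.31 ± 0.18), Lamp5 (-5.18 ± 0.13), Ccn3 (-5.02 ± 0.17) and the calcium channel Ryr2 (-4.91 ± 0.19) were also lower in white matter. All 24 measured genes of the myelin list were higher in white matter (median 4.91), as were all 14 of the oligodendrocyte precursor list (3.1), all 15 of the astrocyte identity list (2.69) and 10 of 11 of the homeostatic microglia list (2.52). Of the synapse list 16 of 22 genes were lower, of the layer V neuron list 10 of 13 and of the axonal cytoskeleton list 13 of 22. These lists passed the set test with a preset correlation, and no list passed with an estimated correlation (the lowest adjusted p = 0.063). In all, 9269 genes differed, 6976 higher and 2293 lower in white matter, over 10 pairs of WT arrays of the same age and replicate number. These pairs need not be single animals, and without the block the count stayed within 1.5 times. The tissues carry different array medians, and the median of all genes was itself 0.31 higher in white matter. After normalizing the tissues jointly that shift was -0.05, 3742 genes were higher and 4472 lower, and 1361 of the 9269 genes had the opposite sign.

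White matter of CNP-KO mice, averaged over the 4 ages, carried higher levels of microglial and astrocytic activation genes than WT. Of the 25 measured genes of the activated microglia list 24 rose, by a median of 1.62 on the log2 scale (adjusted p = 1.8e-48). Among them, the lectin Lgals3 rose by 4.08 ± 0.17, lipoprotein lipase (Lpl) by 3.9 ± 0.2, lysozyme (Lyz2) by 3.83 ± 0.18 and the cystatin Cst7 by 3.08 ± 0.13 (adjusted p = 1.7e-16, 1.8e-14, 2.2e-15 and 5.2e-16). Of 27 reactive astrocyte genes 19 rose and 1 fell (median 0.93), with the protease inhibitor Serpina3n higher by 4.01 ± 0.23, the hyaluronan receptor Cd44 by 3.8 ± 0.16, the oncostatin M receptor Osmr by 2.3 ± 0.14 and S100a6 by 2.04 ± 0.13. Of 14 complement and Fc receptor genes 11 rose (median 1.13), C1qa by 1.79 ± 0.14 and C3ar1 by 1.85 ± 0.13. The lists of activated microglia, reactive astrocytes and complement held with an estimated correlation (adjusted p = 6.4e-05, 6.4e-05 and 0.00062). Other genes with large increases were Lyz1 (3.08 ± 0.13), S100a4 (2.94 ± 0.16) and Serpinf1 (2.14 ± 0.2), though a second Serpinf1 probe set differed by -0.05 and a second Cd44 probe set by 0.21.

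Further lists passed in CNP-KO white matter only with the preset correlation. Of 14 antigen presentation genes 11 rose (median 0.63), among them B2m by 1.19 ± 0.15 and the class II chain Cd74 by 1.32 ± 0.21 (adjusted p = 0.09 for the list with an estimated correlation). Of 17 genes of glycolysis and lactate or glucose transport 9 rose (median 0.24), such as the phosphofructokinase Pfkp by 1.19 ± 0.11 and the lactate transporter Slc16a1 by 0.69 ± 0.08 (adjusted p = 0.09 with an estimated correlation). Of 16 immediate early genes 6 rose and 2 fell, with Fos higher by 1.94 ± 0.16 and Egr1 by 1.19 ± 0.24 (adjusted p = 0.09 with an estimated correlation). The astrocyte identity list had 7 genes higher, Aqp4 by 1.36 ± 0.1, and 3 lower (adjusted p = 0.32 with an estimated correlation). The homeostatic microglia list had 4 genes higher, Fcrls by 2.55 ± 0.17, and 3 lower, Bin1 among them at -0.6 ± 0.08 (adjusted p = 0.22 with an estimated correlation). Genes of axons and neurons were lower: 6 of the 22 axonal cytoskeleton genes, including the kinesins Kif5a (-1.22 ± 0.16) and Kif5c (-1.09 ± 0.12), 3 of 22 synapse genes, 3 of 15 interneuron genes and 3 of 13 layer V neuron genes. With an estimated correlation the adjusted p of these lists was 0.37, 0.39, 0.32 and 0.23. Endothelial and mural genes (6 of 17 lower, Cldn5 at -0.69 ± 0.09) and cell cycle genes (4 of 19 lower, Ccna2 at -0.57 ± 0.11) had an adjusted p = 0.14 each with an estimated correlation.

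Of the remaining lists in CNP-KO white matter none passed the set test. The myelin list held 4 genes that rose and 3 that fell (median 0.03), and Mobp and Mbp differed from WT by 0.04 ± 0.06 and -0.05 ± 0.06. Cholesterol synthesis had 1 gene higher and 1 lower (0.04), oligodendrocyte precursors 2 lower (-0.06), interferon response 5 higher and 1 lower (0.05), T cell 1 and 1 (0.01) and ribosomal proteins 3 lower (-0.1). In 3 lists the median and the mean had opposite signs: axonal injury (5 higher, 1 lower; median -0.04, mean 0.13), unfolded protein response (3 higher, 1 lower; -0.05 and 0.06) and oxidative phosphorylation (4 higher, 7 lower; 0.02 and -0.02). Besides Cnp (-7.4 ± 0.1) and Kif5a, given above, the largest decreases among genes with the same sign at all 4 ages were the following. Pttg1, securin, differed by -2.88 ± 0.24, the Wnt receptor Fzd2 by -1.87 ± 0.14, Vit by -1.14 ± 0.12 and Olfm1 by -1.13 ± 0.16. The Notch target Hes5 differed by -1.13 ± 0.14 and Mettl7a1 by -1.12 ± 0.09. In all, 2392 genes changed, 1398 higher and 994 lower, and 182 of them by more than 2-fold. After quantile normalization the numbers were nearly even, 1328 higher and 1295 lower.

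White matter of PLP-KO mice showed the activation genes as well, together with lower cholesterol synthesis transcripts. Of 17 cholesterol synthesis genes 12 fell and none rose (median -0.42, adjusted p = 0.0017 with an estimated correlation). They included Sqle (-0.81 ± 0.07), Dhcr7 (-0.92 ± 0.08), Fdft1 (-0.77 ± 0.08) and Idi1 (-0.8 ± 0.09), with adjusted p from 3.4e-09 to 5.9e-07. Of 25 activated microglia genes 23 rose (median 0.91), Lyz2 by 3.17 ± 0.18, Lgals3 by 3 ± 0.17, the lectin receptor Clec7a by 2.59 ± 0.2, Lpl by 2.58 ± 0.2 and Cst7 by 1.41 ± 0.13. Of 27 reactive astrocyte genes 12 rose (median 0.35), Cd44 by 2.46 ± 0.16 (a second probe set by 0.1), Serpina3n by 2.25 ± 0.23, Osmr by 1.38 ± 0.14 and Cd14 by 0.9 ± 0.11. Of 14 complement genes 9 rose (median 0.71), Serping1 by 1.42 ± 0.14 and C1qa by 1.28 ± 0.14. With an estimated correlation these lists had adjusted p = 0.00021, 0.0029 and 0.0029. Of 16 immediate early genes 5 rose, with Fos at 1.8 ± 0.16 and the phosphatase Dusp1 at 0.76 ± 0.11 (adjusted p = 0.016 with an estimated correlation).

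Other genes high in PLP-KO white matter were the metalloprotease Adamts1 (2.03 ± 0.15), the stress-induced Gadd45b (1.98 ± 0.12), the receptor Kit (1.87 ± 0.2; a second probe set differed by 0.04) and Tent5c (1.32 ± 0.13). The lowest were B3galnt1 (-1.47 ± 0.15), Anln (-1.19 ± 0.1), Olfm1 (-1.17 ± 0.16), Bcat1 (-1.17 ± 0.18; a second probe set differed by 0.01), Plin3 (-1.07 ± 0.14), the pyruvate dehydrogenase kinase Pdk4 (-1.05 ± 0.28), Tesc (-1.02 ± 0.21) and Pcsk1n (-1.01 ± 0.1). Lists that passed only with the preset correlation were myelin (7 higher, 1 lower, Mag at 0.45 ± 0.1; adjusted p = 0.52 with an estimated correlation), homeostatic microglia (4 higher; 0.2), antigen presentation (3 higher, H2-Aa by 1.6 ± 0.38; 0.33) and unfolded protein response (4 higher, 1 lower; 0.22). The same held for lists that were lower: axonal cytoskeleton (6 of 22, Kif5c at -0.88 ± 0.12; adjusted p = 0.2 with an estimated correlation), synapse (2; 0.2), layer V neuron (3; 0.17), interneuron (0; 0.35), endothelial (1; 0.11) and cell cycle (2; 0.2). The lists of oligodendrocyte precursors (median -0.07), interferon response (-0.11), astrocyte identity (0.07), T cells (-0.01), axonal injury (0.04), oxidative phosphorylation (-0.02), glycolysis (0.1) and ribosomal proteins (-0.04) did not pass. In all, 1421 genes changed, 964 higher and 457 lower, 66 of them by more than 2-fold.

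**Figure D1:**
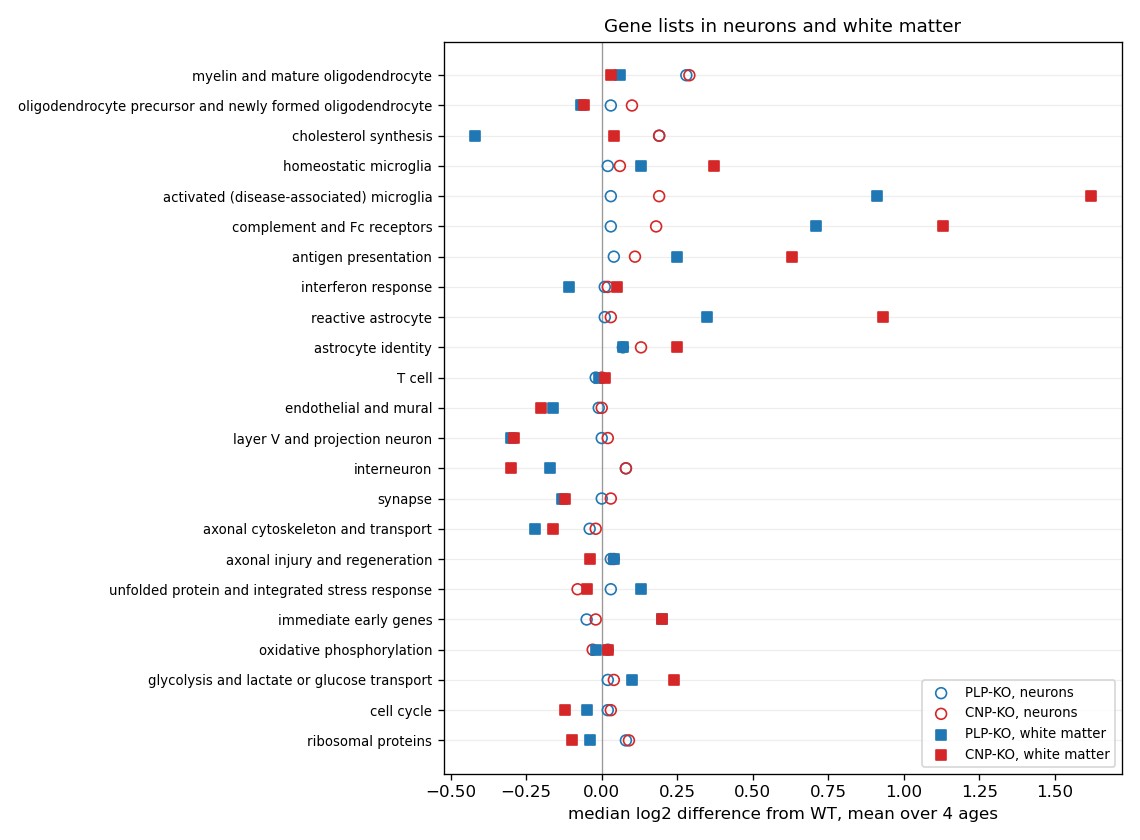
Median log2 difference from WT, averaged over 4 ages, of the measured genes of each of the 23 lists (y axis), for PLP-KO and CNP-KO in neurons (open circles) and white matter (filled squares). The activated microglia list lies at 0.91 in PLP-KO and 1.62 in CNP-KO white matter, and the cholesterol synthesis list at -0.42 and 0.04.

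The mutants were also compared directly. In white matter the cholesterol synthesis list was higher in CNP-KO than in PLP-KO, with 14 of 17 genes (median 0.41; adjusted p = 0.00038 with an estimated correlation). Activated microglia genes (20 of 25 higher, median 0.59), reactive astrocyte genes (19 of 27, 0.62) and complement genes (8 of 14, 0.39) were higher in CNP-KO, and these lists held with an estimated correlation (adjusted p = 0.0012, 0.00022 and 0.011). The highest genes were Serpina3n (1.77 ± 0.22), Cst7 (1.67 ± 0.13) and S100a4 (1.46 ± 0.15), and the lowest Cnp (-7.44 ± 0.09), Pttg1 (-2.82 ± 0.22) and the heat shock gene Hspa1b (-1.9 ± 0.37). Hspa1b differed most at 3 months, with means of 7.3 in CNP-KO and 12.23 in PLP-KO, and averaged 8.53 in both at 1 month. It also varied widely between the WT arrays at 3 months, at 9.4 ± 3.82 (SD, n = 2). In all, 1224 genes differed, 651 higher and 573 lower. In neurons 30 genes differed, 12 higher and 18 lower, led by Serpina3n (1.25 ± 0.16), the immunoglobulin gene Ighm (1.16 ± 0.21) and Kcnj9 (1.12 ± 0.22) and, among the lower, Cnp (-6.04 ± 0.14), Pttg1 (-4.24 ± 0.32) and Krt12 (-3.81 ± 0.11). Other probe sets of Ighm and Kcnj9 were not compared between the mutants. The neuron count moved to 46 when dim genes were left out, to 88 with array weights, and between 16 and 60 when single arrays were left out.

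At single ages, most activated microglia genes of white matter were higher than in WT from 3 months on, whereas Serpina3n in CNP-KO was higher at 1 month already (2.28 ± 0.48). Lgals3 in CNP-KO was 4.83 ± 0.12 at 1 month against 5.05 ± 0.35 in WT (SD, n = 3 and 2), then 10 ± 0.35, 11.07 ± 0.49 and 11 ± 0.26 at 3, 6 and 12 months (SD, n = 3), against 4.85 ± 0.07 (n = 2), 5.2 ± 0.66 and 5.47 ± 0.42 (n = 3) in WT. In PLP-KO it was 4.53 ± 0.21, 7.93 ± 0.47, 10.07 ± 0.71 and 10.03 ± 0.23 (SD, n = 3). Of 25 activated microglia genes 2, 20, 24 and 22 rose in CNP-KO at the 4 ages, and 3, 15, 21 and 20 in PLP-KO, where 1 gene fell at 1 month. The list passed at 3, 6 and 12 months in both mutants, also with an estimated correlation (the highest adjusted p = 0.015), and at 1 month in neither (adjusted p = 0.097 in CNP-KO and 0.99 in PLP-KO). The cholesterol list was lower in PLP-KO at 3, 6 and 12 months with an estimated correlation (adjusted p = 0.039, 0.0041 and 0.0042), by 8, 7 and 7 genes. At 1 month 3 of its genes fell (adjusted p = 0.71 with an estimated correlation). In CNP-KO at 12 months 11 of 14 antigen presentation genes rose (median 1.37; adjusted p = 0.02 with an estimated correlation).

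**Figure D2:**
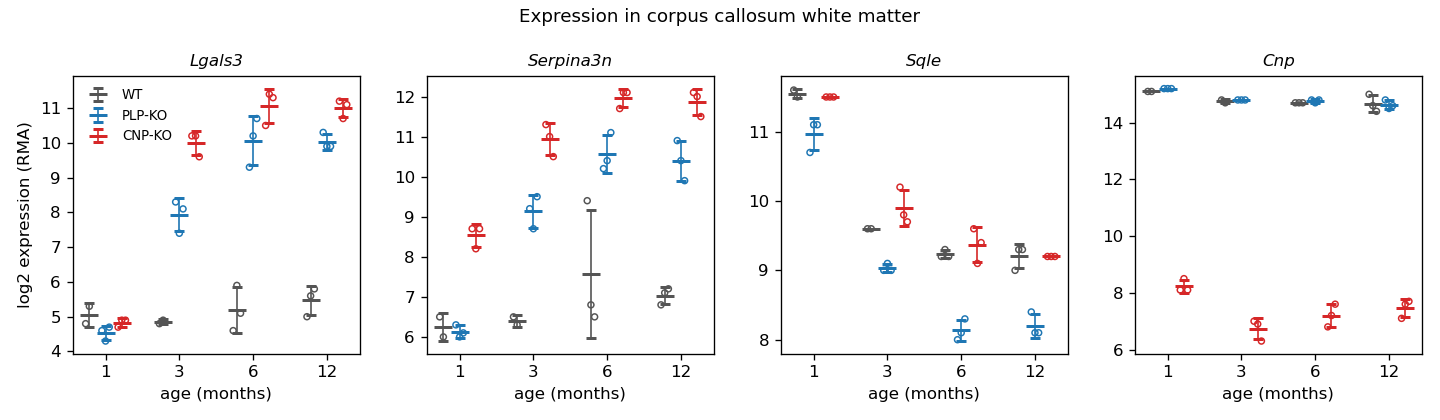
Log2 expression of Lgals3, Serpina3n, Sqle and Cnp in corpus callosum white matter by age in months, for WT, PLP-KO and CNP-KO. Circles are arrays, dashes are means and bars are SD (n = 3, or 2 in WT at 1 and 3 months). At 12 months Lgals3 averaged 5.47 in WT, 10.03 in PLP-KO and 11 in CNP-KO.

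The numbers of genes changed in white matter were, in CNP-KO, 333 at 1 month (185 higher, 148 lower), 716 at 3 months (552, 164), 1422 at 6 months (837, 585) and 1395 at 12 months (792, 603). In PLP-KO they were 595 (355, 240), 848 (569, 279), 475 (345, 130) and 335 (222, 113). Without WT replicate 3 the balance at 12 months turned, to 682 higher and 895 lower in CNP-KO and 231 and 350 in PLP-KO, and the PLP-KO count at 3 months was 216. The highest genes in CNP-KO were Lpl (6.13 ± 0.42), Clec7a (5.92 ± 0.41) and Lgals3 (5.15 ± 0.35) at 3 months, Lgals3 (5.87 ± 0.31), Lyz2 (5.6 ± 0.34) and Clec7a (5.27 ± 0.37) at 6 months, and Lgals3 (5.53 ± 0.31), the protease inhibitor A2m (5.03 ± 0.26) and Cd44 (4.87 ± 0.29) at 12 months. Below Cnp, the lowest were Pttg1 (-3.38 ± 0.5) and Dlx1 (-2 ± 0.35) at 3 months, Snap25 (-2 ± 0.57) and Fzd2 (-1.9 ± 0.27) at 6 months, and Pttg1 (-3.4 ± 0.45) and Gng13 (-2.17 ± 0.38) at 12 months. In PLP-KO the highest were Clec7a (4.55 ± 0.41), Lpl (4.5 ± 0.42) and Lyz2 (3.88 ± 0.38) at 3 months, Lyz2 (4.9 ± 0.34), Lgals3 (4.87 ± 0.31) and Clec7a (4.33 ± 0.37) at 6 months, and Lgals3 (4.57 ± 0.31), Lyz2 (3.8 ± 0.34) and Lpl (3.4 ± 0.37) at 12 months. The lowest were Plin3 (-1.88 ± 0.3), Tppp3 (-1.77 ± 0.27) and Kif5c (-1.75 ± 0.26) at 3 months, B3galnt1 (-1.83 ± 0.29), Tesc (-1.77 ± 0.4) and Hpca (-1.73 ± 0.46) at 6 months, and Rian (-1.83 ± 0.27), Rnf227 (-1.73 ± 0.28) and Nrsn1 (-1.63 ± 0.32) at 12 months. After quantile normalization the share of higher genes fell at 3 months, with 475 of 900 in PLP-KO and 477 of 764 in CNP-KO. With the spread taken from the compared arrays alone, 38 and 93 genes changed in PLP-KO at 3 and 12 months, and 224 and 407 in CNP-KO.

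At 1 month the highest genes in PLP-KO white matter were the alarmin Il33 (3.2 ± 0.3), the prostaglandin synthase Ptgds (2.93 ± 0.22) and Adamts1 (2.68 ± 0.32), and in CNP-KO Serpina3n (2.28 ± 0.48), Adamts1 (1.55 ± 0.32) and Fnbp1 (1.52 ± 0.25). The lowest were Xist (-3.08 ± 0.72), Col6a2 (-2.2 ± 0.38) and Usp18 (-2.08 ± 0.61) in PLP-KO, and Cnp (-6.87 ± 0.2), Xist (-2.98 ± 0.72) and Pttg1 (-2.9 ± 0.5) in CNP-KO. Xist, transcribed from the inactive X chromosome, was at 10.6 in WT 1-month white matter replicate 1 and averaged 4.67 to 4.77 in both mutants at that age, and Il33 in the 2 WT arrays had an SD of 1.13. These 1-month counts depended on WT replicate 2, without which they were 63 in PLP-KO and 33 in CNP-KO. Without replicate 1, the array with high Xist, they were 442 and 291. With the spread taken from the compared arrays alone, limma gave 0 genes in PLP-KO (2379 at an unadjusted p under 0.05) and 3 in CNP-KO. After quantile normalization 296 of 611 genes were higher in PLP-KO and 142 of 318 in CNP-KO.

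Whether the effect of a mutation differed between 12 and 1 month was tested directly. In CNP-KO white matter 806 genes passed, 474 with a more positive effect at 12 months, led by Lgals3 (5.75 ± 0.47), A2m (5.53 ± 0.39) and the class II gene H2-Aa (4.68 ± 1.08; uneven between arrays at 12 months, at 9.27 ± 2.75, SD, n = 3), and 332 with a more negative one, led by Gdf10 (-2.53 ± 0.4), Fnbp1 (-2.12 ± 0.34) and Gng13 (-2.05 ± 0.57). The lists of activated microglia (15 of 25 genes more positive), reactive astrocytes (18 of 27), complement (8 of 14) and antigen presentation (10 of 14) passed with an estimated correlation (adjusted p = 0.00079, 0.00012, 0.0095 and 0.02). In PLP-KO white matter 188 genes passed, 117 more positive, led by Lgals3 (5.08 ± 0.47), Clec7a (4.85 ± 0.55) and Lpl (4.78 ± 0.56), and 71 more negative, led by Il33 (-3.13 ± 0.4), Ptgds (-2.37 ± 0.29) and Gdf10 (-2.17 ± 0.4). Activated microglia (10 of 25), reactive astrocyte (7 of 27) and complement lists (4 of 14) passed with an estimated correlation (adjusted p = 0.0051, 0.0051 and 0.036). Without WT 1-month white matter replicate 2 the counts were 402 and 56. In neurons limma gave 0 genes for PLP-KO (512 at an unadjusted p under 0.05) and 0 for CNP-KO (443). The 3 genes with the smallest p did not pass: Nepro, Tmem216 and Chn2 in PLP-KO (the lowest adjusted p = 0.35), and Prkag2, Lyz1 and Knop1 in CNP-KO (the lowest adjusted p = 0.087).

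Age itself was compared in WT, at 12 against 1 month. In white matter proliferation genes fell, among them the ribonucleotide reductase Rrm2 (-5.22 ± 0.3), Pbk (-3.8 ± 0.26), Mki67 (-3.63 ± 0.22) and Brca1 (-4.1 ± 0.35). Of 19 cell cycle genes 11 fell (median -0.63), and of 17 cholesterol synthesis genes 16 fell (median -1.17), with adjusted p = 0.0069 and 0.013 with an estimated correlation. Rras2 (-4.3 ± 0.31), Cd24a (-4.18 ± 0.57), Il23a (-3.62 ± 0.33) and the radial glia gene Fabp7 (-3.53 ± 0.22) also fell. Il33 rose by 4.07 ± 0.3, Neat1 by 3 ± 0.25, Efcab14 by 3 ± 0.33, the apolipoprotein Apoe by 2.88 ± 0.23, Cavin3 by 2.88 ± 0.26, Klhdc8a by 2.87 ± 0.27, Ptgds by 2.73 ± 0.22 and Sparc by 2.72 ± 0.32. In all, 3993 genes changed, 1799 higher and 2194 lower, and 2018 with the spread of the compared arrays alone. In neuron arrays 245 genes changed, 138 higher and 107 lower. The highest were Il33 (2.4 ± 0.35), the myelin list gene Plekhb1 (2.27 ± 0.27), Ptgds (1.97 ± 0.32), Cks1b (1.77 ± 0.4), Id4 (1.7 ± 0.46), Apoe (1.67 ± 0.26), Car2 (1.6 ± 0.25) and Stard4 (1.47 ± 0.32). The lowest were AY036118 (-2.4 ± 0.22), Bzw2 (-2.33 ± 0.3), Ap2b1 (-2.1 ± 0.24), Vapb (-2 ± 0.18), Marcksl1 (-1.97 ± 0.44), Gm9222 (-1.63 ± 0.33), Postn (-1.6 ± 0.42) and Stk32c (-1.57 ± 0.19). Of the myelin list 5 of 24 genes rose in neuron arrays (median 0.45) and of the astrocyte identity list 3 of 15 (0.33), each with an adjusted p = 0.029 with an estimated correlation. The neuron count was 743 with array weights, 398 without the 3 arrays of low weight, and between 81 and 158 without single arrays. The signal of control transcripts at the 3' end minus that at the 5' end also differed between these ages in WT neuron arrays. From 1 to 12 months it went from 5.4 ± 0.1 to 6.37 ± 0.06 for Gapdh and from 5.33 ± 0.21 to 4.83 ± 0.15 for Actb (SD). For Gapdh it was 6.2 ± 0.72 at 3 months and 5.4 ± 0.35 at 6 months, so the change was not steady. Gapdh in PLP-KO and CNP-KO neuron arrays was at 5.1 ± 0.53 and 5.5 ± 0.26 at 1 month, and 6.5 ± 0.1 and 6.53 ± 0.35 at 12 months. In WT white matter, from 1 to 12 months, Gapdh went from 6.25 ± 0.21 to 5.8 ± 0.26 and Actb from 5.15 ± 0.07 to 5.3 ± 0.36. The bearing of these signals on the counts of either tissue was not tested.

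Neuron arrays of CNP-KO mice, averaged over ages, differed from WT in few genes, among them several of glia. Serpina3n rose by 1.57 ± 0.16, Ptgds by 1.03 ± 0.16, the myelin genes Mobp and Mbp by 1.01 ± 0.12 and 0.78 ± 0.1, and the cathepsin Ctss by 0.76 ± 0.15 (adjusted p = 2.4e-07, 0.00081, 2e-05, 7.2e-05 and 0.014). Kcnj9 (0.96 ± 0.22), Ighm (0.94 ± 0.21) and Spock1 (0.77 ± 0.14) were also higher. No other probe set of Kcnj9 (0.04 and -0.07), Spock1 (-0.04) or Mobp (0.47 and 0.12) passed. Of the other Ighm probe sets only the one at 1.04 passed (adjusted p = 0.014), and the rest lay between -0.14 and 0.18. Of the other Mbp probe sets those at 0.75 to 1.29 passed, and those at -0.23 to 0.43 did not. Of 24 myelin genes 2 rose, 13 when adjusted over the list alone (median 0.29), and of 25 activated microglia genes 2 rose, 14 over the list alone (median 0.19), with Apoe higher by 0.66 ± 0.13. Of 14 complement genes 1 rose, C1qa by 0.72 ± 0.14, and 7 over the list alone (median 0.18), and of 15 astrocyte identity genes 1 rose, Aldoc by 0.37 ± 0.08, and 4 over the list alone (0.13). None of 17 cholesterol synthesis genes rose, and 5 did over the list alone (0.19). These 5 lists passed with an estimated correlation (adjusted p = 0.011, 0.0045, 0.017, 0.011 and 0.011). The myelin and cholesterol lists were also higher in PLP-KO neuron arrays, compared with the same WT arrays. Over the 100 genes highest in white matter over neurons, the median difference in CNP-KO neuron arrays was 0.24 ± 0.03 (bootstrap SE over genes), and 89 were higher.

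Among neuronal and stress genes in CNP-KO neuron arrays, the growth factor Bdnf fell by 0.64 ± 0.14, and the transcription factor Jun rose by 0.64 ± 0.1 and Ddit4 by 0.42 ± 0.09. A second Bdnf probe set was at -0.43 and did not pass (adjusted p = 0.43). The neurofilament genes Nefm and Nefh were at -0.32 ± 0.08 and -0.37 ± 0.1 and did not pass (adjusted p = 0.083 and 0.13), and no gene of the layer V neuron or synapse lists passed. The list of axonal cytoskeleton was lower (median -0.02) and that of axonal injury higher (0.04) with the preset correlation (adjusted p = 0.34 and 0.066 with an estimated correlation). The lists of unfolded protein response (median -0.08), oligodendrocyte precursors (0.1), homeostatic microglia (0.06), antigen presentation (0.11) and ribosomal proteins (0.09) also passed only with the preset correlation (adjusted p = 0.06, 0.17, 0.12, 0.082 and 0.25 with an estimated correlation). Among genes with the same sign at all 4 ages, the largest decreases were in Cnp (-5.54 ± 0.14), Pttg1 (-4.34 ± 0.32) and the keratin Krt12 (-3.5 ± 0.11). Besides Bdnf, they were followed by Gmnn (-0.64 ± 0.13), Nkiras1 (-0.63 ± 0.09), Diablo (-0.61 ± 0.14) and Psmd6 (-0.55 ± 0.08). A second probe set of Diablo was at -0.07 and one of Psmd6 at -0.02, and neither passed (adjusted p = 0.71 and 0.98). In all, 39 genes changed, 25 higher and 14 lower. The count was 179 with array weights, 244 without the 3 arrays of low weight, and 202 without WT 3-month replicate 3 alone. It was 27 without WT 1-month replicate 2, the neuron array with high Xist, and 24 with the spread of the compared arrays only.

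In neuron arrays of PLP-KO mice, limma found 0 genes past the threshold on average over ages (576 at an unadjusted p under 0.05). The 3 genes with the smallest p were Ptgds (0.81 ± 0.16), Fundc2 (0.51 ± 0.11) and the chemokine Ccl25 (-0.48 ± 0.1), each with an adjusted p = 0.24. The myelin list was higher as a set, with a median of 0.28 and 14 of 24 genes past the threshold when adjusted over the list alone, and so was the cholesterol synthesis list, with a median of 0.19 and 2 of 17 genes over the list alone (adjusted p = 0.0038 and 0.0098 with an estimated correlation). Both lists were also higher in CNP-KO neuron arrays, which were compared with the same WT arrays, so chance differences of those arrays enter both results. With the WT arrays split between the mutants, their effects in neurons had a median correlation of 0. The myelin genes with the smallest p were Cldn11 (0.5 ± 0.11), Car2 (0.52 ± 0.12), Ugt8a (0.65 ± 0.17) and Mobp (0.46 ± 0.12), none past the threshold over all genes. The median over the 100 genes highest in white matter was 0.15 ± 0.03 (bootstrap SE over genes), and 80 were higher. The ribosomal protein list passed only with the preset correlation (median 0.08; adjusted p = 0.52 with an estimated correlation). No other list passed, activated microglia (0.03) and axonal cytoskeleton (-0.04) included. The count was 1 with array weights and 4 without the 3 arrays of low weight.

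At single ages in neurons, 4 genes changed in CNP-KO at 1 month: Serpina3n rose by 1.7 ± 0.31, and Cnp (-5.8 ± 0.27), Pttg1 (-4.37 ± 0.64) and Krt12 (-3.47 ± 0.22) fell. At 3 months 226 changed (192 higher, 34 lower), with the enkephalin gene Penk highest (1.83 ± 0.29), followed by Tk2 (1.53 ± 0.31) and Serpina3n (1.5 ± 0.31), and with Cnp (-5.73 ± 0.27), Pttg1 (-5.43 ± 0.64) and Krt12 (-3.8 ± 0.22) lowest. At 6 months 59 changed (37, 22), with Lyz1 (3.2 ± 0.44), Mitf (2.07 ± 0.36) and Dcbld1 (1.87 ± 0.31) highest, and Cnp (-5.13 ± 0.27), Krt12 (-3.57 ± 0.22) and Pcsk1 (-1.43 ± 0.3) lowest. At 12 months 7 changed (4, 3), with Lyz1 (3.07 ± 0.44), Ptgds (1.63 ± 0.32) and Lyz2 (1.23 ± 0.2) highest, and Cnp (-5.5 ± 0.27), Pttg1 (-4.9 ± 0.64) and Krt12 (-3.17 ± 0.22) lowest. The activated microglia list was higher at 6 and 12 months (median 0.5 and 0.23; adjusted p = 0.0014 and 0.012 with an estimated correlation). The 100 genes highest in white matter were also higher at these ages (median 0.3 ± 0.05 and 0.2 ± 0.03, bootstrap SE over genes). They were higher at 1 and 3 months as well (0.23 ± 0.04 and 0.2 ± 0.05). In PLP-KO neurons 1 gene changed at 1 month, Nepro (-1.03 ± 0.17), and 10 at 6 months (8 higher, 2 lower), with Morc3 (1.53 ± 0.28), Cdca4 (1.4 ± 0.26) and Anxa1 (1.33 ± 0.22) highest and Sh3d19 (-1.77 ± 0.35) and Cspp1 (-1.4 ± 0.21) lowest. At 3 and 12 months limma gave 0 genes (666 and 356 at an unadjusted p under 0.05). The genes with the smallest p were Cdc42se1, Ttc7b and Gria1 at 3 months (adjusted p = 0.62 each), and Agpat3, Slc25a15 and Tmem40 at 12 months (the lowest adjusted p = 0.4). These counts moved with single arrays, with normalization and with the choice of spread. The CNP-KO count at 3 months ranged over 42 to 451 with single arrays left out, and the 6-month balance was 32 higher and 33 lower with quantile normalization and 73 and 81 without the 3 arrays of low weight. With the compared arrays alone the CNP-KO count was 4 at 3 months and 3 at 6 months, and with array weights the PLP-KO count at 12 months was 523.

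**Figure D3:**
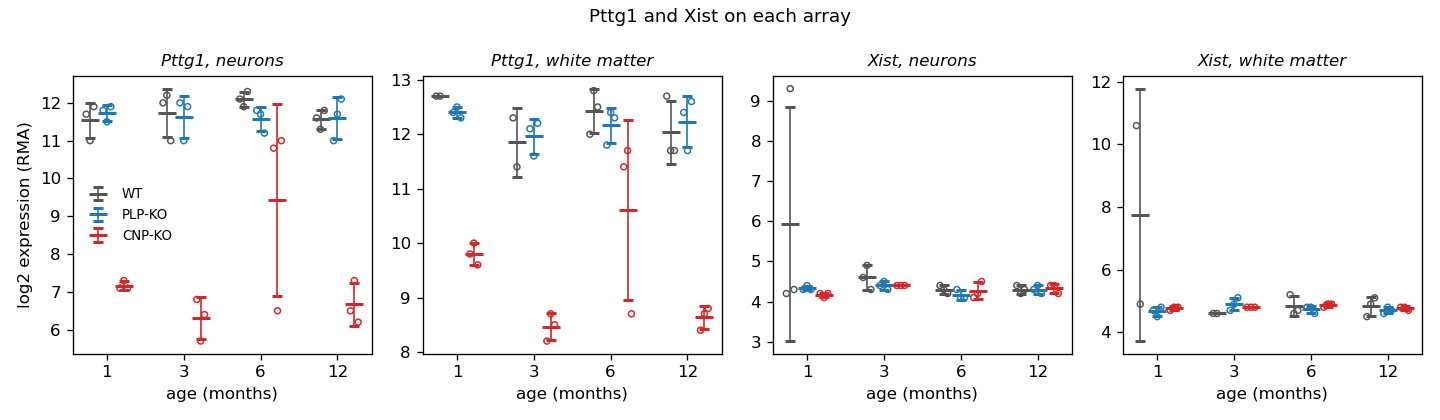
Log2 expression of Pttg1 and Xist on each array of neurons and white matter by age in months, for WT, PLP-KO and CNP-KO. Circles are arrays, dashes are means and bars are SD (n = 3, or 2 in WT white matter at 1 and 3 months). Pttg1 was at 10.8, 6.5 and 11 in the CNP-KO neuron arrays at 6 months, and Xist at 9.3 in WT 1-month neuron replicate 2 and 10.6 in WT 1-month white matter replicate 1.

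Because both mutants were compared with the same WT arrays, chance differences of those arrays enter both effects. Across genes, which are not independent replicates, the averaged effects of PLP-KO and CNP-KO correlated with r = 0.79 in white matter, where unchanged groups simulated with shared WT arrays gave a median of 0.55 and at most 0.89. The covariance of the effects was 0.0492, against a median of 0.00453 in those simulations. With the WT arrays split between the mutants the median over 20 splits was 0.6. In white matter 668 genes rose in both mutants and 308 fell in both, where independent calls would give 109 and 36.6 and the simulated unchanged groups gave at most 1 and 0, and 5 changed in opposite directions. With split WT arrays the medians were 388 and 139. In neurons the correlation was 0.4, below the simulated median of 0.52, and with split WT arrays it was 0.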

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

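The tests of the loss of Cnp and of the other probe sets of Pttg1 were chosen only after the result was seen, and so was the 1-month pattern of both mutants, whose test was written before its own value was seen. It was taken up after an earlier hypothesis on the 1-month arrays. That hypothesis is among the other observations.

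The effect of a mutation differed between the tissues, by a test of the interaction, in 491 genes for PLP-KO (326 more positive and 165 more negative in white matter) and in 1192 for CNP-KO (723 and 469). That test fitted all 70 arrays as independent, with 1 spread per gene for both tissues. The median residual SD was 0.218 in neurons and 0.178 in white matter. In CNP-KO, Lgals3 differed by 3.86 ± 0.19 more in white matter than in neurons, and Mobp by -0.97 ± 0.14. In neurons the group means of Lgals3 ran from 3.7 to 5, near the lowest deposited value of 3, so it was hardly detected there. The effect in white matter differed between 12 and 1 month in 188 genes for PLP-KO and 806 for CNP-KO.

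Among the 1555 probe sets that no gene is assigned to, which the comparisons do not use, some changed against WT on average over ages: 3 in PLP-KO neurons (all lower), 7 in CNP-KO neurons (1 higher, 6 lower), 92 in PLP-KO white matter (48, 44) and 189 in CNP-KO white matter (84, 105). In PLP-KO white matter the 3 that fell most were at -5.48 ± 0.08, -5.04 ± 0.09 and -4.85 ± 0.1, and in PLP-KO neurons the same probe sets were at -3.99 ± 0.25, -1.31 ± 0.19 and -4.97 ± 0.39. In white matter 1 unnamed probe set rose most in both mutants, by 3.72 ± 0.16 in PLP-KO and 4.75 ± 0.16 in CNP-KO. The files do not pair these probe sets with genes.

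Pttg1 was lower in CNP-KO arrays of both tissues. A fault of a single probe set is argued against by the other Pttg1 probe sets, at -0.88 ± 0.1 and -1.34 ± 0.19 in white matter. Whether loss of Cnp alone lowers it stays open. All 24 CNP-KO arrays had low Cnp and were below the lowest WT array of their tissue and age in Pttg1. For 3 of them, all at 6 months, the gap was no more than 1 log2 unit, a bound set after the values were seen. For another 6-month neuron array it was 1.1. At 6 months Pttg1 was at 10.8, 6.5 and 11 in CNP-KO neurons and 11.4, 11.7 and 8.7 in white matter. WT arrays of other ages were as low as some of these. WT white matter was at 11.4 at 3 months (replicate 3) and 11.7 at 12 months (replicates 2 and 3). WT neurons were at 11 at 1 month (replicate 2) and 3 months (replicate 3). The remaining CNP-KO arrays were below every WT array of their tissue. Low Cnp alone does not account for the differences among these arrays. A variant carried along with the targeted locus may also account for the lower Pttg1, since Pttg1 and Krt12 lie on the chromosome of Cnp. Of the 1039 tested genes of that chromosome, 882 lie nearer to Cnp than Pttg1 and 72 nearer than Krt12, so that Pttg1 lies far from it. Of the 100 nearest genes 17% ± 3.76 (binomial SE) changed in CNP-KO white matter, against 19.3% of the others (Fisher's exact test, p = 0.61). That met the bound set in advance against this explanation, but by less than its spread. Cnp, Pttg1 and Krt12 were left out of both shares, and a variant confined to single genes would not move them. Krt12, which lies nearer to Cnp than Pttg1, differed by -3.5 ± 0.11 in CNP-KO neurons and -0.83 ± 0.16 in white matter. Its other probe set was at -1.82 and -0.03. At 6 months Krt12 was at 4.6, 5.1 and 5.3 in CNP-KO neurons, against 8.8, 8.3 and 8.6 in WT.

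Glial genes were higher in CNP-KO neuron arrays. For Mobp and Mbp, at 0.04 and -0.05 in white matter, the values argue against a mirror of the same change in CNP-KO white matter. Of the 25 genes that rose in neuron arrays, however, 14 rose in white matter too (2.82 if independent), so this is not decided for the set. The white matter was corpus callosum, and glia beside the cortical neurons were not measured. More RNA of neighbouring glia in the CNP-KO captures may account for the glial genes. The median over the 100 genes highest in white matter over neurons was 0.24 ± 0.03 (bootstrap SE over genes, not arrays). The endothelial list, however, had a median of 0, and PLP-KO neuron arrays also had a median of 0.15. The 100 genes were picked with the same WT neuron arrays, which favours genes that are low in them. Both mutants share those arrays, so their chance differences enter both medians. Expression of glial genes changed in the neurons themselves, or more glia beside them, was not tested.

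At 1 month, 209 genes changed in the same direction in white matter of both mutants (118 higher, 91 lower). That the 2 WT arrays of this age stand apart is consistent with their later course: the median effect of both mutants, signed by the 1-month direction, was 0.82 at 1 month and at most 0.1 at 3, 6 and 12 months, where other WT arrays serve. The mutants differed from each other in 23 genes at 1 month and in 692, 293 and 292 later. An early, passing effect of both mutations would give the same values, and it cannot be told apart from the WT arrays with 2 arrays at that age.

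Other splits of the arrays were counted for each comparison of groups of at least 3. On average over ages, only the real split of 100 gave as many genes for CNP-KO in neurons (39, against 13 in the highest other split) and in white matter (2392 against 1083), PLP-KO in white matter (1421 against 345), CNP-KO against PLP-KO in neurons (30 against 4) and white matter (1224 against 179), and the tissues in WT (9269 against 7384), so a chance split does not account for these counts. Where the real count was 0, every split reaches it and the splits test nothing. This holds for all 100 splits of PLP-KO in neurons (highest other 2; limma, 576 at an unadjusted p under 0.05) and of the age differences in neurons (highest other 1 in PLP-KO and 13 in CNP-KO; limma, 512 and 443 at an unadjusted p under 0.05). Comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. In CNP-KO neurons at 1, 3, 6 and 12 months the real counts were 4, 226, 59 and 7 and the highest others 1, 6, 20 and 1, and in WT neurons at 12 against 1 month 245 and 1. In white matter at 6 and 12 months they were 475 and 335 against 0 and 3 in PLP-KO, and 1422 and 1395 against 8 and 20 in CNP-KO. In PLP-KO neurons at 1 and 6 months the real counts were 1 and 10 and the highest others 1 and 54, with 2 and 4 of the 10 splits reaching the real count. At 3 and 12 months the real count was 0, which all 10 splits reach (highest others 26 and 0; limma, 666 and 356 at an unadjusted p under 0.05). Splits with 26 and 54 genes, far above the real counts, point to some structure of the samples, and what it is was not tested.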

How the results depend on the processing

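The alternatives without the 1-month arrays, without the 3 low-weight neuron arrays and with joint normalization were chosen after seeing the data. No named gene past the threshold reversed its direction under any alternative run for it, nor did any list call of the averages against WT. List calls of the other comparisons were not rerun under these alternatives. The balance of higher and lower genes turned in several counts. Between the tissues it was 3742 higher and 4472 lower with joint normalization (6976 and 2293 without), and 1361 of the 9269 genes had the opposite sign. With quantile normalization it was 296 and 315 in PLP-KO and 142 and 176 in CNP-KO white matter at 1 month (355 and 240, and 185 and 148, without), and 32 and 33 in CNP-KO neurons at 6 months (37 and 22), where it was 73 and 81 without the low-weight arrays. For CNP-KO against PLP-KO in white matter it was 571 and 582 without dim genes and 837 and 876 with array weights (651 and 573 otherwise). With the compared groups alone it turned only where at most 4 genes were left, and with single arrays left out in 3 counts of neurons and 7 of white matter, such as 231 and 350 in PLP-KO and 682 and 895 in CNP-KO at 12 months without WT replicate 3. Of 346 named genes past the threshold, 262 passed under every alternative that covers them, and of 44 list calls of the averages against WT 15 did. Blocking by replicate number moved no count by more than 1.5 times, nor did all probe sets, the averages without the 1-month arrays or, in the tissue comparison, no block or joint normalization. The averaged counts of white matter stayed within 1.5 times under every alternative, at 1314 to 1652 in PLP-KO and 1941 to 2726 in CNP-KO apart from single arrays left out. The fit of the compared groups was not made for differences between ages or the tissues, all probe sets were run for the averages against WT only, and the tissue comparison was not run without the low-weight arrays together.

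Where counts moved, the cause was not tested, except that leaving out dim genes tests fewer genes and leaving out arrays uses fewer samples. Leaving out dim genes gave 46 genes for CNP-KO against PLP-KO in neurons and 5739 between the tissues. Quantile normalization gave 133 and 11 for CNP-KO neurons at 3 and 12 months, and trend and robust estimation 32 and 11 at 6 and 12 months. Array weights gave 1 gene for PLP-KO neurons on average, 0 at 1 month (limma, 754 at an unadjusted p under 0.05), 18 at 6 months, 523 at 12 months and 4 for the difference between ages. They gave 179 for CNP-KO neurons on average, 93 and 68 at 6 and 12 months, 88 for CNP-KO against PLP-KO and 743 for age in WT neurons. In white matter they gave 174 and 767 at 12 months in PLP-KO and CNP-KO and 506 for the CNP-KO difference between ages. The compared groups alone gave 24 for CNP-KO neurons on average and 4, 3 and 3 at 3, 6 and 12 months, and for PLP-KO neurons 0, 1 and 0 at 1, 3 and 6 months (limma, 697 and 674 at an unadjusted p under 0.05 for the counts of 0). In white matter they gave 0, 38 and 93 in PLP-KO at 1, 3 and 12 months (limma, 2379 at an unadjusted p under 0.05 for the count of 0), 3, 224 and 407 in CNP-KO, and 2018 for age in WT. Without the 3 low-weight arrays, PLP-KO neurons had 4 genes on average and 17, 72 and 1 at 3, 6 and 12 months, CNP-KO neurons 244 on average and 542 and 154 at 3 and 6 months, and WT age in neurons 398.

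With single arrays left out, counts in neurons ranged over 0 to 3 (PLP-KO on average; highest without PLP-KO 6-month replicate 1, with 2 without WT 3-month replicate 3 and 1 without WT 12-month replicate 1), 27 to 202 (CNP-KO on average; highest without WT 3-month replicate 3) and 16 to 60 (CNP-KO against PLP-KO; without PLP-KO 6-month replicate 3 and CNP-KO 1-month replicate 1, with 19, 19, 17, 48 and 17 without CNP-KO 1-month replicate 3, CNP-KO 3-month replicates 1 and 3, PLP-KO 6-month replicate 1 and PLP-KO 12-month replicate 2). For PLP-KO they were 0 to 3 at 1 month (0 without WT replicates 1 or 3 or PLP-KO replicate 2, 2 without WT replicate 2, 3 without PLP-KO replicate 3), 0 to 13 at 3 months (highest without WT replicate 3) and 0 to 53 at 6 months (without PLP-KO replicates 3 and 1, with 23, 33 and 4 without WT replicates 1, 2 and 3). For CNP-KO they were 42 to 451 at 3 months (42, 353 and 451 without WT replicates 1, 2 and 3 and 79, 51 and 82 without those of CNP-KO), 18 to 96 at 6 months (36, 96 and 18 without WT replicates 1, 2 and 3), 6 to 21 at 12 months (highest without CNP-KO replicate 1) and 0 to 3 for the difference between ages (3 without 12-month replicate 3, 1 without 1-month replicate 2). WT age gave 81 to 158 (129, 158 and 81 without 1-month replicates 1, 2 and 3, and 113, 87 and 138 without those at 12 months). In white matter PLP-KO ranged over 63 to 448 at 1 month (63 without WT replicate 2, 307 without PLP-KO replicate 3), 216 to 1105 at 3 months (216 without WT replicate 3, 417 and 255 without PLP-KO replicates 2 and 3), 288 to 439 at 6 months (288 without PLP-KO replicate 3) and 163 to 581 at 12 months (581 without WT replicate 3, and 163, 217 and 219 without PLP-KO replicates 1, 2 and 3). CNP-KO ranged over 33 to 472 at 1 month (33 without WT replicate 2, 126 and 197 without CNP-KO replicates 1 and 2), 400 to 617 at 3 months (400 without WT replicate 3) and 921 to 1307 at 6 months (921 without CNP-KO replicate 2). The differences between ages ranged over 56 to 339 in PLP-KO (56 without WT 1-month replicate 2, 315 and 339 without WT 12-month replicates 1 and 3, 114 and 104 without PLP-KO 1-month replicates 1 and 3, and 114 each without PLP-KO 12-month replicates 1 and 3) and 402 to 915 in CNP-KO (402 without WT 1-month replicate 2). The lowest averaged count of CNP-KO against WT in neurons, 27, came without WT 1-month replicate 2. An arm left with 1 array is assumed to vary like the other groups.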

Other observations

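Some genes outside the lists were shared by the tissues of CNP-KO mice. Of the 25 genes that rose in neuron arrays, the astrocyte genes Mlc1 and Kcnj10 rose in white matter by 0.79 ± 0.09 and 0.25 ± 0.07, and Pdlim2 by 0.89 ± 0.1. These genes were chosen for naming after their values were seen. In white matter Fos was 9.37 ± 0.5 in CNP-KO and 9.1 ± 0.4 in PLP-KO at 12 months against 6.67 ± 0.47 in WT (SD, n = 3 each), and at 1 month 7.3 ± 0.6 and 7.7 ± 0.1 (n = 3 each) against 7.55 ± 0.35 (n = 2). Sqle averaged 11.55 at 1 month and 9.2 at 12 months in WT white matter, 10.97 and 8.2 in PLP-KO, and 11.5 and 9.2 in CNP-KO.

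Of the 70 arrays, 2 stood apart in Xist. In neurons, WT 1-month replicate 2 had Xist at 9.3 and the Y-linked Eif2s3y at 3.5, and in white matter WT 1-month replicate 1 had Xist at 10.6 and Eif2s3y at 8.6. The arrays of the same age and number in the other tissue had Xist at 4.9 (white matter replicate 2) and 4.2 (neuron replicate 1). Replicate numbers at 1 month thus did not match across the tissues in Xist. On the other neuron arrays Eif2s3y was at 6.3 or more. The values of WT 1-month neuron replicate 2 are thus those of a female and go against its label of male. That array served in every neuron contrast that uses WT at 1 month. WT 1-month white matter replicate 1 held both transcripts, and whether it was mixed was not tested. In all other groups Xist averaged 4.17 to 4.9.

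An earlier hypothesis, prompted by the high Il33 and Ptgds in PLP-KO white matter at 1 month, was that genes that rise with age were higher there. The test could not decide it, since it used genes that change from 3 to 12 months, whereas Il33 and Ptgds rose from 1 to 3 months in WT (8.9 to 12.8 and 11.1 to 13.95) and were at 12.97 and 13.83 at 12 months. Over the 722 genes that changed between 3 and 12 months in WT white matter (396 rising, 326 falling), the median difference of PLP-KO from WT at 1 month, signed by that change, was -0.02 ± 0.02 (bootstrap SE), and 48.6% went the same way. In CNP-KO it was -0.03 ± 0.01, with 45.8%. Its 2 explanations had been written in advance and were tested. For WT 1-month white matter arrays that stand apart, the median signed difference of PLP-KO from CNP-KO was 0 ± 0.01, within the bound that explanation had set. As that set lacks the genes that prompted the hypothesis, this decides nothing, a reading made after the value was seen. For PLP-KO arrays that come from older mice, the cell cycle list differed from WT by a median of -0.12 ± 0.12, where it fell from 1 to 3 months in WT by a median of 0.4 ± 0.31, which is too wide to decide.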
